A study of Homo sapiens with 8 samples.

How the data were processed

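The data were deposited tables of gene expression for 8 RNA-seq libraries from 4 human thyroid cancer cell lines, with 1 library per group and no replicate library. 8505C and CAL-62 each gave a library after an siRNA against NR1D1 and a library after a control siRNA. TPC-1 and FTC-133 each gave a library with an NR1D1 vector and a library with an empty vector. RNA was extracted with Trizol, RNA integrity numbers were at least 6.8, and libraries were made with a standard Illumina preparation, per the labels. Reads had been checked with FastQC and MultiQC, trimmed with Trimmomatic 0.38 and counted with featureCounts 2.0.0 on GRCh38, per the submitters' processing notes. The aligner, the annotation release, the strandedness of counting, the siRNA sequences and the time of harvest were not given in the sources used here.

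The deposited tables for 8505C and CAL-62 held TPM, and each of their columns summed to 1000000. The deposited tables for TPC-1 and FTC-133 were also named TPM by the authors, but their columns summed to 253330.3, 261161.0, 261469.4 and 256453.4. Value times union exon length in GENCODE 29 summed to 1.001, 1.002, 1.005 and 1.004 times the sum that FPKM has, so these tables were read as FPKM and rescaled to a sum of 1000000. The tables held 58884 gene identifiers, of which 58472 had a symbol in the name table used here, 58611 were in GENCODE 29 and 243 were in neither. Placeholder names taken from genomic clones were counted as no symbol, a reading settled only once the tables had been read.

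Read numbers were recovered as value times exon length on the scale that made the smallest values whole. Between 71.6% and 74.6% of nonzero values came out whole within 0.02 of a read, and between 92.7% and 93.7% of values of 1 to 10 reads did. The recovered numbers were too often not whole for a count model, so they served for intervals on NR1D1 and to say which genes rested on few reads. Recovered totals were 14.9, 17.91, 17.93, 12.86, 23.18, 22.54, 16.64 and 16.11 in units of 1e6 reads, in the order 8505C, CAL-62, TPC-1 and FTC-133 with the control first. Genes above 0 numbered 23787, 25679, 25620, 25128, 24390, 24716, 23511 and 23968. The correlation of log2 values between the libraries of a line was 0.942, 0.941, 0.961 and 0.941. The pairing of libraries came from the shared cell line alone.

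Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1) for genes with a mean TPM of at least 1 over the 8 libraries, 17595 genes in all. Each model held a term for cell line and a prior spread that followed expression, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 4-line comparison set the NR1D1-higher library of each line against the NR1D1-lower library, with 3 residual degrees of freedom. The siRNA comparison and the vector comparison each rested on 2 lines and shared a spread with 2 residual degrees of freedom. When a line was left out, its comparison kept 1 pair and took its spread from the lines of the other approach. A further comparison asked whether siRNA and vector effects, each oriented by NR1D1, differed. Each approach was used in its own lines, so a difference between approaches cannot be told from a difference between those lines. The limma p-values measure only the spread between these lines, with each line as 1 observation. Within a line, 2-fold changes were counted without a test among genes with a mean TPM of at least 1 in its libraries.

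A set of 41 gene lists was fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. At the preset correlation camera treats member genes as nearly independent observations, so its p-values do not measure the spread between lines alone. For each line, the median change of a list was placed among 10000 random lists drawn from 20 expression bins and given as a percentile. Members were also counted after adjustment over the list alone.

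Genes were named by rules fixed before the data were examined. They had a symbol, a biotype other than pseudogene and a mean TPM of at least 5. The 4-line comparison gave 12 genes per direction by mean change, each with a log2 ratio of at least 0.3 in every line. The siRNA and vector comparisons gave 10 per direction by the smaller ratio of the pair of lines, each single line gave 6 per direction, and each list past the threshold gave 4 members. Small RNAs met these rules on very few reads and are given as counts. Most clock genes were named, as were some genes that passed with a mean TPM of at least 5, a choice made once the tables had been read.

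The methods were tried on simulated data with each gene's own mean and spread and with known changes planted. The spread came from the model with separate siRNA and vector terms, which leaves out disagreement between the approaches. The 4-line comparison called 13 of 67 genes planted at 2-fold, 41 of 67 at 4-fold and 56 of 66 at 8-fold, with 5 unchanged genes called. These 4-line numbers may therefore be too high for the real data. The siRNA comparison called 0 of 67, 0 of 67 and 0 of 66, though 54, 61 and 66 of these had an unadjusted p under 0.05. Restricted to a mean TPM of at least 5 (11174 genes), the siRNA comparison called 0, 15 and 46, with 2 unchanged genes called. A count of 0 for the siRNA comparison over all 17595 genes is therefore no sign that genes stayed unchanged, even by 8-fold. The vector comparison was not simulated.

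Alternatives chosen before the data were examined were a pseudocount of 0.1, no expression filter, a mean TPM of at least 5, rescaling within each line by a trimmed mean of log ratios (30% trimmed at each end), a prior without a trend, an estimated correlation for the 4-line lists, leaving out each line in turn and dropping the term for cell line. Alternatives added once the tables had been read were protein-coding genes alone (12594 genes), the deposited FPKM without rescaling, the list settings applied to the siRNA and vector lists, the settings applied to agreement between lines, and the omission of genes with siRNA-like heptamers.

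Matches to siRNA seeds were looked for among 9860 genes with a mean TPM of at least 5 and a 3' UTR of at least 50 bases, using 1 coding transcript per gene. Each of 15335 heptamers present in at least 100 of these genes was scored by the mean change of the genes carrying it. Changes were limited to 3 log2 units and adjusted for UTR length, GC content and expression, and the scores were set against 100 shuffles. The scan ranked a planted heptamer first in 16 of 20 trials at a log2 effect of -0.1, in 20 of 20 at -0.2 and in 0 of 20 at 0. Genes lower in both siRNA lines were compared with 10000 sets matched on UTR length, and histone genes with 10000 lists drawn from the 100 genes nearest in exon length and expression.

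Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps. Splicing, sequence variants and protein levels were not analysed here, and a few items are not reported here.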

Results

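NR1D1 encodes REV-ERB alpha, a nuclear receptor of the circadian clock that binds ROR elements and represses genes such as BMAL1. The libraries set reduced NR1D1 in 8505C and CAL-62 cells, by siRNA, beside raised NR1D1 in TPC-1 and FTC-133 cells, by vector. All 4 lines come from human thyroid cancers.

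NR1D1 was lower after its siRNA in both siRNA lines. It was 18.23 TPM in 8505C control and 11.24 after siRNA, a ratio of 0.616 (95% interval 0.499 to 0.759). In CAL-62 it was 21.97 and 10.14, a ratio of 0.462 (0.383 to 0.553). The median gene in CAL-62 also had a log2 ratio of -0.278, beside -1.043 for NR1D1. The CAL-62 ratio thus overstates the fall of NR1D1 relative to other genes, and it was not computed after rescaling. The vector lines started far higher and their values differed less. Which exons the vector carries was not given, so these values may not measure all of its NR1D1 RNA. NR1D1 was 189.95 TPM with the empty vector and 208.68 with the NR1D1 vector in TPC-1, a ratio of 1.1 (1.046 to 1.154). In FTC-133 it was 105.37 and 136.89, a ratio of 1.299 (1.205 to 1.4). These intervals cover counting error only, because each group had 1 library. NR1D1 passed no joint test, with a siRNA log2 change of -0.85 (limma, Benjamini-Hochberg adjusted p = 0.33) and a 4-line difference of 0.55 (adjusted p = 0.938). THRA overlaps NR1D1 by 1081 bases on the other strand, and the strand setting of counting was not given. THRA went from 22.64 to 27.08 TPM in 8505C, from 6.6 to 5.58 in CAL-62, from 9.41 to 9.17 in TPC-1 and from 34.08 to 33.41 in FTC-133.

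**Figure D1:**
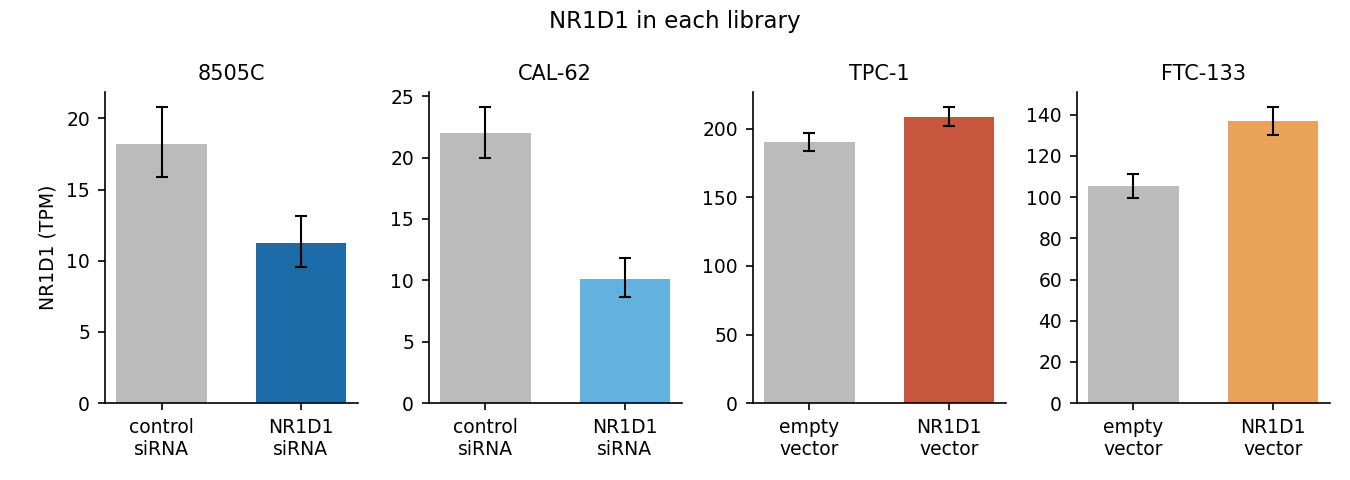
NR1D1 in TPM for each of the 8 libraries, with control libraries in grey and treated libraries in colour. Bars show 95% intervals from counting error only.

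Clock genes gave mixed values. BMAL1, the activator that REV-ERB alpha represses, went from 12.61 to 16.85 TPM after siRNA in 8505C and from 12.13 to 20.11 in CAL-62. With the NR1D1 vector it went from 8.26 to 6.76 in TPC-1 and from 4.84 to 3.25 in FTC-133, so all 4 lines had BMAL1 lower where NR1D1 was higher by label. Its siRNA log2 change of 0.54 did not pass (limma adjusted p = 0.489). NPAS2, a partner of BMAL1, had log2 ratios of 0.43, 0.83, 0.32 and -0.59 in 8505C, CAL-62, TPC-1 and FTC-133. CLOCK, the main partner of BMAL1, had -0.26, -0.09, 0.02 and -0.43. The repressor CRY1 had 0.19, -0.52, -0.59 and 0.40, and NFIL3, a repressor of D-box genes, had -0.42, 0.46, 0.02 and -0.40. The ROR-element genes as a list did not pass in the 4-line comparison (camera adjusted p = 0.12, and 0.796 with an estimated correlation), at percentiles of 56.6, 98.31, 58.68 and 2.69 among random lists.

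Genes driven through E-boxes did not move together either. TEF, a D-box activator, went from 13.55 to 31.02 TPM in 8505C and from 11.81 to 14.26 in CAL-62 after siRNA, and from 22.56 to 20.06 in TPC-1 and from 19.89 to 9.45 in FTC-133 with the vector. DBP, of the same family, had log2 ratios of 0.44, 0.22, -0.28 and -0.51 in that order, and HLF had -0.18, -0.05, 0.82 and 0. PER1 went from 4.17 to 10.61 TPM in 8505C, from 1.37 to 1.61 in CAL-62, from 52.94 to 28.64 in TPC-1 and from 17.09 to 20.37 in FTC-133. PER2 had log2 ratios of 0.11, -0.24, -0.74 and 0.17, and PER3 had 0.37, 0.25, -0.29 and 0.21. CRY2 had -0.36, -0.33, -0.38 and 0.11, and NR1D2, the paralog of NR1D1, had 0.33, -0.23, -0.68 and -0.20. BHLHE40, a repressor at E-boxes, had 0.30, -1.20, -0.24 and 0.64, and BHLHE41 had 0.09, 0.11, -0.60 and 0.37. The deubiquitinase gene USP2 had 1.22, -0.06, 0.24 and 0.67, and CIART had -0.52, 0.07, 0.48 and 0.20. The E-box list did not pass either (camera adjusted p = 0.161, and 0.796 with an estimated correlation), at percentiles of 88.45, 93.02, 2.71 and 82.19. The time of harvest was not given, and the clock phase of each library is unknown here.

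After NR1D1 siRNA, some genes had large changes of the same direction in 8505C and CAL-62. SEMA7A, a membrane-anchored semaphorin, went from 4.21 to 54.1 TPM in 8505C and from 41.5 to 252 in CAL-62. COL1A1, a chain of type I collagen, had log2 ratios of 1.89 and 2.93, and PLAT, which encodes tissue plasminogen activator, had 2.08 and 2.53. ACLY, which makes cytosolic acetyl-CoA for lipid synthesis, had 2.77 and 1.34. S100A10, the annexin A2 partner, went from 1557 to 203 TPM in 8505C and from 339 to 41.1 in CAL-62. Over all 17595 genes limma called 0 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.166, for S100A10). At unadjusted p under 0.05 there were 2114 genes, 791 higher and 1323 lower, where 880 are expected by chance. Rescaling by the trimmed mean turned that split to 1272 and 1191. On the CAL-62 pair alone, without 8505C, there were 1113, 264 higher and 849 lower, and without CAL-62 there were 1192, 845 higher and 347 lower. Among genes with a mean TPM of at least 5, 77 passed, 38 higher and 39 lower, with adjusted p from 0.0054 to 0.0499. The same 77 genes had adjusted p from 0.166 to 0.274 over all 17595 genes, and up to 0.611 over the settings that kept all lines. Among protein-coding genes 64 passed, of which 57 were shared with the 77.

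Among the 38 genes that rose at that setting, SEMA7A had a mean log2 change of 2.99 (SE 0.33, 7.93-fold, limma adjusted p = 0.0054). Its adjusted p ran from 0.0054 to 0.611 over the settings that kept all lines. PLAT rose by 2.31, PLSCR4, a phospholipid scramblase gene, by 2.63 and COL1A1 by 2.41. PLAUR, the urokinase receptor gene, rose by 1.79 and COL5A1 by 2.35. The receptor kinase gene KIT rose by 2.76, with 1.95 in 8505C and 3.57 in CAL-62. ACLY rose by 2.06, the growth factor gene CSF2 by 2.40, the apelin gene APLN by 2.40 and the pentraxin gene PTX3 by 2.29. The adhesion gene CEACAM1 rose by 2.5, the tetraspanin gene CD82 by 2.05 and the Wnt ligand gene WNT5B by 1.71. SIRPG rose by 2.75, TMEM87B by 2.75, LAMP3 by 2.29 and the monocyte receptor gene CD14 by 2.30. Of these 38 genes 35 had a 3' UTR that could be searched, and 14 carried one of the heptamers that scored highest in both siRNA lines after adjustment for UTR length, GC content and expression. Such heptamers were no more common among genes 2-fold higher in both lines than elsewhere, at 31.2% and 32.7%. OLFML3 and the adhesion gene NTM had log2 ratios of 2.60 and 2.52, and of 2.64 and 2.31. NTM passed among protein-coding genes and OLFML3 passed in neither of these restricted sets.

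Among the 39 genes that fell, S100A10 dropped by 2.97 (SE 0.33, 7.85-fold, limma adjusted p = 0.0054, running to 0.611 over the settings that kept all lines). SELENOT, an endoplasmic reticulum selenoprotein gene, fell by 2.45, and ANO6, a calcium-activated scramblase gene, by 2.43. UBAC2 fell by 2.37 and GTF2E1, a subunit of general transcription factor TFIIE, by 2.29. The glycolytic gene PGAM1 fell by 2.08, the purine synthesis gene PAICS by 1.74, ADO by 2.03 and BAG6, a chaperone gene, by 2.15. AAGAB fell by 2.13. Of these 39 genes 33 had a 3' UTR that could be searched. Of the 33, 27 carried ATGAGCA, CATGAGC, AATCCTA or AAATCCT, heptamers of low score in both siRNA lines. Only ATGAGCA exceeded the largest absolute score of 100 shuffles in both lines. In CAL-62, where that largest score was 5.56, the others had -4.9, -5.45 and -4.01. Among genes 2-fold lower in both lines 69.0% carried one, beside 30.5% of others, without matching on UTR length. The heptamers were picked on these same libraries, so some excess was built in and these shares are no independent evidence. SELENOT, ANO6, GTF2E1, S100A10, AAGAB and ADO carried such a heptamer, and UBAC2 and BAG6 did not. At the main filter limma called 0 genes with and without the genes that carry siRNA-like heptamers, and genes at unadjusted p under 0.05 went from 2114 to 1143 without them, with 4660 fewer genes tested. The settings ran from 0 to 77 genes. The rule for the siRNA lines also gave 5 small RNAs, 2 higher and 3 lower.

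Of 41 lists, 19 passed for siRNA with camera at the preset correlation and 0 with an estimated correlation. Cholesterol synthesis genes were higher in 23 of 24 members (median log2 0.78, camera adjusted p = 2.04e-12, adjusted p = 0.512 with an estimated correlation). DHCR7, the last enzyme of the pathway, had a log2 change of 1.53, MVD 1.20 and MVK 1.18. Of the 24, 9 passed when adjusted over the list alone. Fatty acid synthesis genes were higher in 15 of 20 (median 0.44, camera adjusted p = 0.000364, adjusted p = 0.57 with an estimated correlation), and 5 passed adjusted over the list alone. ACLY led them, then the desaturase gene FADS2 with 1.46, FASN with 1.26 and ACSS2 with 1.21.

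Collagens and matrix genes were higher in 34 of 38 (median 0.85, camera adjusted p = 2.37e-12, adjusted p = 0.392 with an estimated correlation), with 7 passing adjusted over the list alone. COL13A1 had a log2 change of 2.37 and the fibrillin gene FBN1 1.69, beside COL1A1 and COL5A1. Matrix proteases and their regulators were higher in 24 of 29 (median 0.63, camera adjusted p = 3.26e-09, adjusted p = 0.392 with an estimated correlation), with 7 passing adjusted over the list alone. MMP2, a gelatinase gene, had 1.78 and TIMP3, a metalloprotease inhibitor gene, 1.79, the latter from 3.53 in 8505C and 0.05 in CAL-62. Integrins and adhesion genes were higher in 23 of 28 (median 0.42, camera adjusted p = 4.29e-05, adjusted p = 0.512 with an estimated correlation), led by ALCAM with 1.59 and ITGB4 with 1.58. TGF-beta genes had 15 of 22 higher, with a median of only 0.08 and a mean of 0.35 (camera adjusted p = 0.0108, adjusted p = 0.57 with an estimated correlation). TGFBR1, the type I receptor gene, had 1.53, LTBP1 1.35 and LTBP2 1.31, and 3 passed adjusted over the list alone. The TGF-beta median was 0.43 in 8505C and -0.06 in CAL-62, at percentiles 99.4 and 98.7 among random lists. Mesenchymal genes were higher in 15 of 23 (median 0.21, camera adjusted p = 0.0108, adjusted p = 0.57 with an estimated correlation), and fibroblast markers in 9 of 10 (median 0.23, camera adjusted p = 0.018, adjusted p = 0.512 with an estimated correlation). Endothelial and pericyte markers were higher in 7 of 8 (median 0.62, camera adjusted p = 0.003, adjusted p = 0.57 with an estimated correlation). Their median was 1.06 in 8505C and 0.07 in CAL-62, at percentiles 99.86 and 84.86 among random lists. MCAM had 1.17 and PDGFRB 1.34, the latter from 2.60 in 8505C and 0.08 in CAL-62.

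Interferon-stimulated genes were higher in 30 of 36 (median 0.52, camera adjusted p = 1.82e-07, adjusted p = 0.392 with an estimated correlation), though 0 passed adjusted over the list alone. IFIT2, IFIT1, HERC5 and ISG15, all induced by interferon, had log2 changes of 1.28, 1.12, 1.07 and 1.06. NF-kB targets and cytokines were higher in 25 of 33 (median 0.36, camera adjusted p = 0.000499, adjusted p = 0.8 with an estimated correlation). CSF2 led them, then the adhesion receptor gene ICAM1 with 1.69, the lymphotoxin gene LTB with 1.54 and the cytokine gene IL11 with 1.46. Immune cell markers were higher in 5 of 5 measured (median 0.46, camera adjusted p = 0.0181, adjusted p = 0.512 with an estimated correlation), with CD14 on top. MAPK output genes were higher in 17 of 26 (median 0.28, camera adjusted p = 0.0293, adjusted p = 0.912 with an estimated correlation), with the EGFR ligand gene HBEGF at 1.62 and ETV4 at 1.11. Their median was 0.80 in 8505C and -0.17 in CAL-62, at percentiles 100 and 97.61 among random lists. G2/M genes were higher in 39 of 42 (median 0.34, camera adjusted p = 0.000393, adjusted p = 0.912 with an estimated correlation), but this rested on 8505C. There the median was 1.07 with 42 of 42 members higher, while CAL-62 had a median of -0.46 with 2 of 42 higher, at percentile 52.94 among random lists. TOP2A, a mitotic topoisomerase gene, had 1.70 in 8505C and 0.15 in CAL-62, and the centromere gene CENPA had a mean of 0.92.

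Replication-dependent histone genes were lower in 11 of 11 (median -1.08, camera adjusted p = 8.45e-08, adjusted p = 0.392 with an estimated correlation, fry adjusted p = 0.0282), and 8 passed adjusted over the list alone. H1-2, a linker histone gene, had -1.78, H2BC21 -1.76, H2AC6 -1.61 and H2BC8 -1.28. Most histone mRNAs have no poly(A) tail, and how RNA was selected for the libraries was not given. Ribosomal protein genes were lower in 36 of 36 (median -0.80, camera adjusted p = 1.48e-11, adjusted p = 0.8 with an estimated correlation), with RPL23 at -1.06 and RPS6 at -1.05. Respiratory chain genes were lower in 28 of 30 (median -0.47, camera adjusted p = 0.000499, adjusted p = 0.912 with an estimated correlation), with UQCRQ at -1.03 and NDUFB3 at -0.88. This rested on CAL-62, with a median of -0.87 (-0.33 with that of random lists subtracted, percentile 0.12), while 8505C had -0.04 (percentile 42.56). The share of TPM from mitochondrial RNA went from 57.22% to 67.85% in CAL-62 and from 29.28% to 28.6% in 8505C, and the median gene in CAL-62 had a log2 ratio of -0.278. The ribosomal median there was -1.27, or -0.62 with that of random lists subtracted. NRF2 and ferroptosis genes were lower in 22 of 27 (median -0.45, camera adjusted p = 0.00187, adjusted p = 0.512 with an estimated correlation). Their median was -0.52 in 8505C (percentile 0.01) and -0.53 in CAL-62, only -0.16 there with that of random lists subtracted (percentile 12.41). FTL, the ferritin light chain gene, had -1.25, the glutathione synthesis genes GCLC and GCLM had -1.16 and -1.09, and NQO1 had -0.98. Heat shock genes were lower in 16 of 20 (median -0.35, camera adjusted p = 0.0365, adjusted p = 0.912 with an estimated correlation), with HSPA4 at -1.13 and HSPE1 at -0.96. The median was -0.71 in CAL-62, only -0.19 with that of random lists subtracted (percentile 8.28), and -0.06 in 8505C (percentile 36.84). Of the 19 lists that passed for siRNA, 14 also passed with pseudocount 0.1, with a mean TPM of at least 5, after rescaling and without heptamer carriers, except that endothelial and pericyte markers had too few members for the higher filter. Single lines were not left out for these lists.

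Lists that did not pass for siRNA had medians from -0.44 to 0.10. Rescaling by the trimmed mean turned those of G1/S, recombination, epithelial, autophagy and YAP or TEAD genes from below to above 0. Glycolysis was at -0.14, hypoxia at 0.07, mitochondrially encoded mRNAs at 0.09, heme synthesis at -0.21, G1/S at -0.07 and homologous recombination with Fanconi genes at -0.08. The p53 targets were at -0.17, the unfolded protein response at 0.10, the integrated stress response at -0.17, epithelial genes at -0.06 and Wnt targets at -0.23. Autophagy was at -0.10, the BCL2 family at -0.14, immediate early genes at -0.20, metallothioneins at -0.17 and neural markers at 0.05. Thyroid differentiation genes were at 0.02, with 9 of 22 measured, so most genes of the thyroid hormone program were below the filter. YAP and TEAD targets were at -0.07, though 2 passed adjusted over the list alone, with WWTR1, which encodes TAZ, at -1.47 and AMOTL1 at -1.41. Glucocorticoid targets were at -0.44, also with 2 passing adjusted over the list alone, and FKBP5 was at -1.20. The clock lists were at 0.02 for ROR-element genes, 0.07 for E-box genes and 0.01 for regulators, where BTRC was at -0.77 and FBXW11 at -0.65.

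With the NR1D1 vector, TPC-1 and FTC-133 shared few changes. IGFBP3, which encodes an IGF-binding protein, went from 677 to 3219 TPM in TPC-1 and from 34 to 178 in FTC-133. SORT1, a sorting receptor gene, had log2 ratios of 3.32 and 2.15. EREG, an EGFR ligand gene, went from 410 to 116 TPM in TPC-1 and from 11.4 to 0.77 in FTC-133, and CXCL8, which encodes interleukin 8, from 2350 to 739 and from 552 to 129. Over all 17595 genes limma called 0 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.272), with 784 at unadjusted p under 0.05, 499 higher and 285 lower, where 880 are expected by chance. That number was 1358 without TPC-1, where the test rested on the FTC-133 pair alone, 514 without 8505C, 501 without CAL-62 and 365 with FPKM as deposited. Among genes with a mean TPM of at least 5, 7 passed, 4 higher and 3 lower, with adjusted p from 0.0244 to 0.0465. The same 7 genes had adjusted p from 0.272 to 0.301 over all 17595 genes, and up to 1 over the settings that kept all lines. Among protein-coding genes 22 passed, of which 5 were shared with the 7.

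IGFBP3 rose by 2.30 (SE 0.31, 4.93-fold, limma adjusted p = 0.0244) and SORT1 by 2.74 (SE 0.35, adjusted p = 0.0244) at that setting, where the range over the settings that kept all lines was 0.0106 to 0.953 for both. LINC01605 rose by 3.10 and 1 gene without a symbol by 2.80. UGT8, a glycolipid synthesis gene, fell by 3.93, LONRF3 by 3.27 and EREG by 2.31. The settings ran from 0 to 22 genes. Other genes named by rule were the receptor gene GFRA1 with log2 ratios of 2.57 and 2.84, LZTS1 with 2.81 and 3.16, the tubulin gene TUBB2B with 3.35 and 2.46 and LOXL4, a lysyl oxidase family gene, with 2.57 and 2.08. Lower were the chromatin organizer gene SATB1 with -3.79 and -2.30, LINC02392 with -2.07 and -2.57, and CGB8 with -1.73 and -2.38, where near-identical copies make the counting uncertain. CXCL8 had -1.67 and -2.09. A further 3 small RNAs were named in each direction.

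For the vector, interferon-stimulated genes were higher in 29 of 36 (median log2 0.42, camera adjusted p = 8.09e-05, adjusted p = 0.938 with an estimated correlation). IFITM1 had a log2 change of 1.17, IFIT3 0.86, EPSTI1 0.80 and MX1 0.74, so the interferon genes had the same sign as after siRNA. Collagens and matrix genes were higher in 27 of 38 (median 0.32, camera adjusted p = 0.0136, adjusted p = 0.938 with an estimated correlation). The basement membrane genes COL4A1 and COL4A2 had 2.60 and 2.08, THBS1 had 1.91 and COL13A1 had -1.99. YAP and TEAD targets were higher in 17 of 22 (median 0.31, camera adjusted p = 0.0136, adjusted p = 0.946 with an estimated correlation), with ANKRD1 at 1.44, NUAK2 at 1.35 and CCN2 at 1.13. Their median was 0.06 in TPC-1 (percentile 94.43) and 0.38 in FTC-133 (percentile 99.77). Histone genes were lower in 10 of 11 (median -0.45, camera adjusted p = 0.00291, adjusted p = 0.938 with an estimated correlation), with H4C8 at -1.08 and H1-2 at -0.73. Homologous recombination and Fanconi genes were lower in 21 of 25 (median -0.24, camera adjusted p = 0.0136, adjusted p = 0.946 with an estimated correlation), with FANCB at -0.77, NBN at -0.58 and BRCA2 at -0.54. Their median was -0.09 in TPC-1 and -0.43 in FTC-133. G1/S genes were lower in 32 of 37 (median -0.21, camera adjusted p = 0.0136, adjusted p = 0.946 with an estimated correlation), with ATAD2 at -0.73 and CCNE2 at -0.45. In all, 6 of 41 lists passed for the vector, 3 of them also with pseudocount 0.1, with a mean TPM of at least 5, after rescaling and without heptamer carriers. Single lines were not left out here either.

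**Figure D2:**
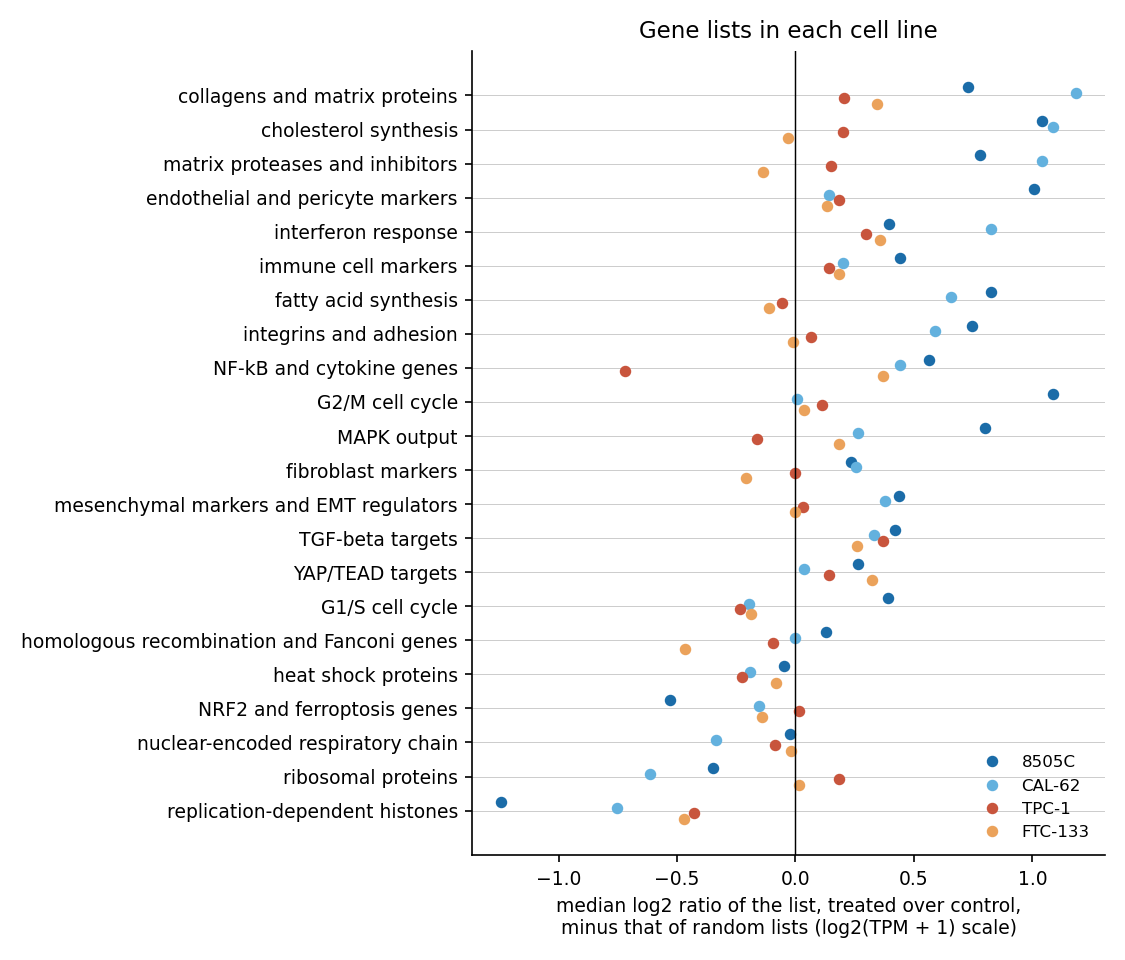
Median log2 ratio of treated over control for gene lists, less the median of expression-matched random lists. Each dot is 1 cell line.

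Across 4 lines, oriented so that NR1D1 was higher, no gene passed. ALDH5A1, a GABA-degrading dehydrogenase gene, went from 6.08 to 1.58 TPM in 8505C and from 18.3 to 4.61 in CAL-62 after siRNA. With the vector it went from 10.3 to 21.8 in TPC-1 and from 4.35 to 8.62 in FTC-133. WWTR1 went from 101 to 43.4 and from 38.5 to 10.8 after siRNA, and from 103 to 216 and from 23.4 to 33.6 with the vector. The 3' UTRs of ALDH5A1, WWTR1, IGFBP3 and GBP2 carry a heptamer of low score in both siRNA lines, of those given above. COL13A1, ABI3BP and ANGPTL2 ran the other way, at mean log2 differences of -2.18, -2.22 and -1.35. limma called 0 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.731, for a microRNA gene), with 720 at unadjusted p under 0.05, 413 higher and 307 lower, where 880 are expected by chance. Rescaling by the trimmed mean gave 340 higher and 448 lower. Without 8505C there were 467, and without CAL-62 there were 426, 197 higher and 229 lower. The 4-line comparison gave 0 in every setting tried.

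Among the genes named by rule other than small RNAs, IGFBP3 had a mean difference of 1.40 with higher NR1D1, followed by TRMT12 with 1.31, ALDH5A1 with 1.28, the interferon-induced GTPase gene GBP2 with 1.25, WWTR1 with 1.13, the protease gene PRSS23 with 1.06 and DPH1-AS1 with 1.02. Lower with NR1D1 were PLSCR4 with -1.98, PTX3 with -1.70, the lipolysis inhibitor gene G0S2 with -1.46, NGEF with -1.28 and the neprilysin gene MME with -1.26. SERPINA1, which encodes alpha-1 antitrypsin, had -1.14 and the carbonic anhydrase gene CA12 had -1.12. The rule also gave 7 small RNAs, 5 higher and 2 lower. One direction in all 4 lines was found for 1775 genes, 10.09% of those tested. A share of 12.5% holds for independent lines with either sign equally likely. The siRNA lines were correlated and ratios of 0 counted as no direction, so these shares cannot be strictly compared. Of the 1775 genes 242 had a log2 ratio of at least 0.3 in every line.

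Of 41 lists, 13 passed for the 4-line comparison with camera at the preset correlation, and 8 passed without 8505C. None passed with an estimated correlation. Ribosomal protein genes were higher with NR1D1 in 36 of 36 (median 0.45, camera adjusted p = 8.39e-11, adjusted p = 0.796 with an estimated correlation). Their medians of treated over control were -0.37 in 8505C and -1.27 in CAL-62 but 0.13 in TPC-1 and 0.07 in FTC-133, so siRNA carried the result. Respiratory chain genes were higher in 25 of 30 (median 0.22, camera adjusted p = 0.0487, adjusted p = 0.842 with an estimated correlation). Their medians of treated over control were -0.04 in 8505C, -0.87 in CAL-62, -0.16 in TPC-1 and 0.04 in FTC-133. CAL-62 thus carried that result. YAP and TEAD targets were higher in 14 of 22 (median 0.31, camera adjusted p = 0.0487, adjusted p = 0.796 with an estimated correlation). Those medians were 0.23, -0.49, 0.06 and 0.38 in the same order. In 8505C these targets thus went the other way, and in CAL-62 they lay at percentile 60.45 among random lists. Cholesterol synthesis genes were lower with NR1D1 in 23 of 24 (median -0.35, camera adjusted p = 1.37e-07, adjusted p = 0.796 with an estimated correlation), and fatty acid synthesis genes in 16 of 20 (median -0.37, camera adjusted p = 0.000112, adjusted p = 0.796 with an estimated correlation). NF-kB targets were lower in 25 of 33 (median -0.30) and matrix proteases in 23 of 29 (median -0.51), both at a camera adjusted p of 8.75e-06 and an adjusted p = 0.796 with an estimated correlation. Collagens were lower in 26 of 38 (median -0.24, camera adjusted p = 0.000318), with 2 passing adjusted over the list alone, G2/M genes in 36 of 42 (median -0.18, 0.000472) and integrins in 22 of 28 (median -0.22, 0.000895), each at an adjusted p = 0.796 with an estimated correlation. MAPK output was lower in 21 of 26 (median -0.17, camera adjusted p = 0.0163), homologous recombination and Fanconi genes in 18 of 25 (median -0.10, 0.0487) and fibroblast markers in 8 of 10 (median -0.25, 0.0487), again at an adjusted p = 0.796 with an estimated correlation. With the vector alone the medians were 0.32 for collagens, 0.04 for cholesterol synthesis, 0.04 for matrix proteases and 0.00 for integrins, so these lists also rested on siRNA. Fatty acid synthesis had treated over control medians of 0.831, 0.229, -0.111 and -0.065 in the same order of lines. Its vector values lay at percentiles 29.41 and 16.76, so it rested mainly on siRNA. MAPK output had 0.798, -0.174, -0.223 and 0.229, so FTC-133 went the other way. Fibroblast markers had 0.3, 0.125, 0 and -0.176. Recombination and Fanconi genes rested on the vector, with a siRNA median of -0.08 and a vector median of -0.24. NF-kB targets had a vector median of -0.74 in TPC-1 and 0.41 in FTC-133. The G2/M result rested on 8505C alone. Its medians of treated over control were 1.07 in 8505C, -0.46 in CAL-62, 0.03 in TPC-1 and 0.08 in FTC-133. Cholesterol synthesis, fatty acid synthesis, matrix proteases, NF-kB targets and ribosomal proteins, 5 of the 13, also passed with pseudocount 0.1, with a mean TPM of at least 5, after rescaling, without heptamer carriers and without each line in turn.

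The comparison of siRNA with vector, each oriented by NR1D1, looked for genes that both treatments moved the same way. OLFML2B, an olfactomedin-domain gene, had log2 ratios of 2.49, 1.82, 1.91 and 1.85 in 8505C, CAL-62, TPC-1 and FTC-133. Its paralog OLFML2A had 3.45, 1.47, 1.86 and 1.47. Over all 17595 genes limma called 0 after Benjamini-Hochberg adjustment (smallest adjusted p = 0.344), with 1653 at unadjusted p under 0.05, 807 higher and 846 lower, where 880 are expected by chance. Without 8505C there were 996, 314 higher and 682 lower, and without CAL-62 there were 1093, 783 higher and 310 lower. Among genes with a mean TPM of at least 5, 7 passed, all with a positive sum of siRNA and vector changes. OLFML2B had a sum of 4.03 (SE 0.44, adjusted p = 0.0111, running to 0.734 over the settings that kept all lines), OLFML2A 4.12, SORT1 3.80 and SEMA7A 3.02, and the other 3 were small RNAs. SORT1 was also higher after siRNA, with 0.82 and 1.32, whereas SEMA7A had 0.11 in TPC-1 and -0.05 in FTC-133, so its sum rested on siRNA. The 7 genes had adjusted p from 0.344 to 0.367 over all 17595 genes. Among protein-coding genes 22 passed, and the settings ran from 0 to 22.

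Large changes were also ranked line by line, for which 1 library per group allows no test. Some of these genes moved in other lines too. KIT, given for CAL-62, had a log2 ratio of 1.95 in 8505C, and LONRF3 and ABI3BP were named above for more than 1 line. In 8505C FGFBP1, which encodes an FGF carrier, went from 15.9 to 203 TPM. In CAL-62 KIT went from 3.93 to 57.6 TPM and TNFSF18, a TNF family ligand gene, from 14.1 to 0. In TPC-1 ANGPTL4, a lipoprotein lipase inhibitor gene, went from 0.28 to 40 TPM, VAMP8 from 1.14 to 82 and LAPTM5 from 14.5 to 472. KRT81 and HTATIP2 had log2 ratios of 4.58 and 4.23. MAGEA6, ABI3BP, WLS, MRFAP1L1 and LONRF3 had -4.96, -4.82, -4.27, -4.10 and -4.05 there. In FTC-133 AEBP1 went from 0.56 to 381 TPM and the adhesion receptor gene VCAM1 from 1.57 to 198. PAGE5, IGFBP7, LINC01029 and CHRDL1 had log2 ratios of 6.97, 5.76, 5.42 and 5.07 in that line. The cancer-testis genes MAGEB2, CTAG2 and MAGEC2 had -5.77, -5.44 and -5.18, and COX7A1, ANO3 and VGF had -4.92, -4.85 and -4.85. Near-identical copies make the counting of MAGEA6 and CTAG2 uncertain.

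Within each line many genes were 2-fold apart, a good part of them small RNAs on few reads. There were 1968 higher and 967 lower in 8505C, with 581 small RNAs among them, and 861 higher and 1729 lower in CAL-62, with 523. In CAL-62 rescaling turned the split to 1407 higher and 806 lower. TPC-1 had 1015 higher and 849 lower, with 439 small RNAs, and FTC-133 had 1611 higher and 1141 lower, with 675.

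Several lists stood out in single lines. Hypoxia targets lay at percentiles of 19.72, 100, 99.77 and 1.76 among random lists in 8505C, CAL-62, TPC-1 and FTC-133. NF-kB targets lay at 99.98, 99.98, 0 and 99.95, and immediate early genes at 97.62, 0.22, 0 and 95.84, so TPC-1 with the vector had both at the bottom. TGF-beta genes lay at 99.4, 98.7, 99.95 and 98.47, interferon-stimulated genes at 99.72, 100, 99.96 and 99.93, and collagens at 100, 100, 99.74 and 100. Cholesterol synthesis genes lay at 100, 100, 98.6 and 37.67.

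Over all tested genes, agreement between lines oriented by NR1D1 was found for the siRNA pair alone. Some lists still moved alike as treated over control, with interferon-stimulated genes, collagens and TGF-beta genes high among random lists in every line. The log2 ratios of 8505C and CAL-62 correlated at 0.354 over all tested genes, against -0.013 for TPC-1 and FTC-133. Of 691 genes 2-fold apart in both siRNA lines 550 had the same direction and 141 the opposite one. In TPC-1 and FTC-133 these numbers were 256 and 231 of 487. Between a siRNA line and a vector line, oriented by NR1D1, the correlations were -0.016, -0.078, -0.083 and -0.05. In the same order they were -0.044, -0.107, -0.15 and -0.046 with a mean TPM of at least 5. A negative value here means that changes of treated over control ran weakly alike.

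**Figure D3:**
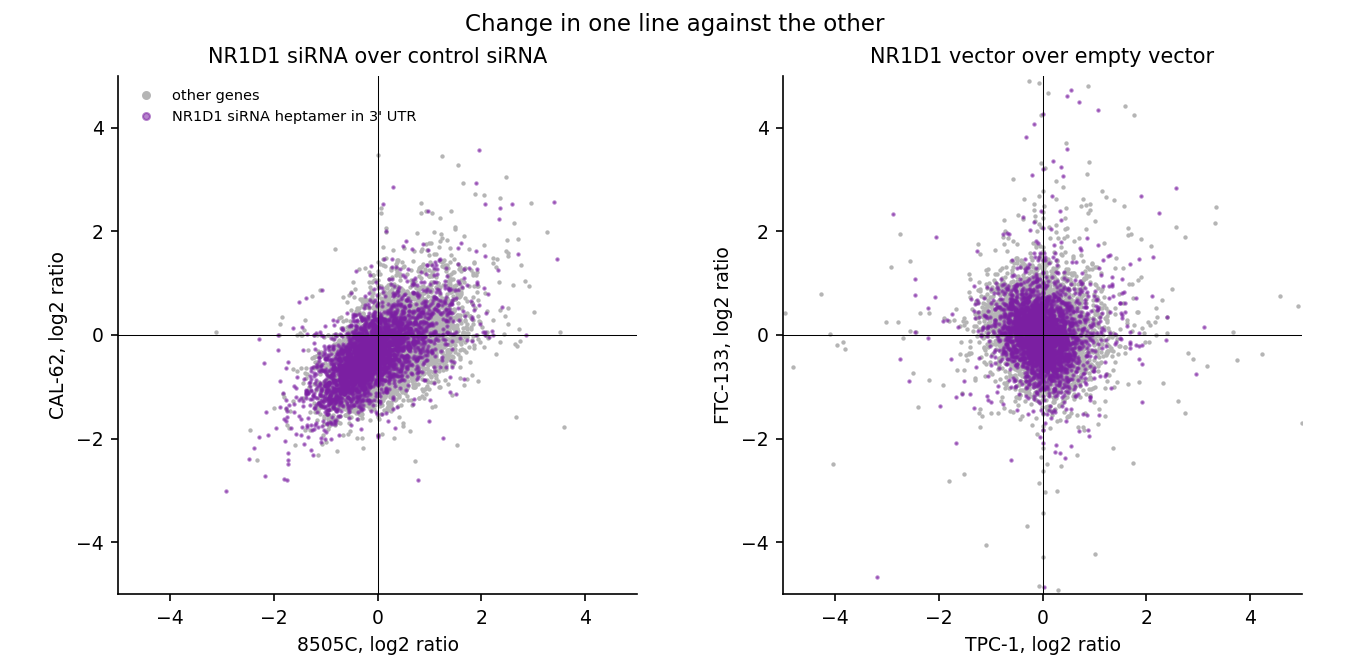
Log2 ratios of treated over control in 8505C against CAL-62 and in TPC-1 against FTC-133. Genes whose 3' UTR carries a heptamer matching the candidate NR1D1 siRNA are purple.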

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

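Of the tests in this part, the S-phase comparison was chosen only after the result was seen, while the length and poly(A) tests were written before. The lists below had siRNA and vector effects that differed once oriented by NR1D1, either because both treatments moved them the same way or because siRNA moved them and the vector did little. As siRNA and vector were used in different lines, such a difference cannot be told from a difference between the lines. Values are medians of the siRNA and vector log2 changes added together, with camera adjusted p values, and the smallest adjusted p with an estimated correlation was 0.367.

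Collagens and matrix genes had a median sum of 1.034 (camera adjusted p = 1.48e-11, adjusted p = 0.367 with an estimated correlation). Interferon-stimulated genes had 0.844 (4.33e-10, and 0.367 estimated). Cholesterol synthesis had 0.786 (6.31e-09, and 0.636 estimated), though its vector median was small. Replication-dependent histones had -1.421 (7.88e-09, and 0.367 estimated). Ribosomal proteins had -0.648 (3.46e-06, and 0.95 estimated). Matrix proteases had 0.912 (6.69e-06, and 0.618 estimated). TGF-beta genes had 0.462 (0.00171, and 0.636 estimated) and respiratory chain genes -0.503 (0.00171, and 0.984 estimated). NRF2 and ferroptosis genes had -0.648 (0.00262, and 0.636 estimated). Integrins had 0.559 (0.00262, and 0.636 estimated). Endothelial and pericyte markers had 1.001 (0.00372, and 0.636 estimated). Heat shock genes had -0.664 (0.00633, and 0.95 estimated), G2/M genes 0.297 (0.0288, and 0.984 estimated) and immune cell markers 0.968 (0.0384, and 0.636 estimated).

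The histone list was lower in the treated library of all 4 lines, with medians of -1.22, -1.08, -0.47 and -0.43. Under-counting of short transcripts may lower such genes, but against random lists matched on exon length and expression the histone median lay below 95% of lists in 4 lines (percentiles 0.0, 0.31, 1.26 and 0.87), which counts against it. A different carry-over of RNA without poly(A) tails could also act: 3 lines had a median of such RNAs above the limit set before, but only 6 of 17 were measured and they went both ways, so that test decided nothing. Fewer cells in S phase is a hypothesis for the other 3 lines, where the highest G1/S percentile was 1.79. In 8505C the G1/S genes lay at percentile 99.87, which counts against it there. The RNA of G1/S genes does not measure the share of cells in S phase, so the test cannot exclude it as a shared cause. The shared cause of the histone pattern thus stays open.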

How the results depend on the processing

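No list passed with an estimated correlation, in place of 13 for the 4-line comparison, 19 for siRNA and 6 for the vector. The 4-line lists numbered 8 without 8505C, 10 without CAL-62, 12 without TPC-1, 15 without FTC-133 and 8 without genes carrying siRNA-like heptamers, and the cause was not tested.

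For siRNA the calls were 0 at the main setting, 77 with a mean TPM of at least 5, 64 among protein-coding genes and 18 with FPKM as deposited. For the vector they were 7 with a mean TPM of at least 5 and 22 among protein-coding genes, and for the difference between approaches also 7 and 22. Leaving out any line gave 0, and with a line out the siRNA or vector test it belongs to rested on 1 pair. With no replicate block the 4-line comparison called 0, with 51 at unadjusted p under 0.05. For the vector 491 genes were at unadjusted p under 0.05 with a mean TPM of at least 5.

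The correlation of 8505C with CAL-62 was 0.235 with pseudocount 0.1, 0.246 with no filter, 0.506 with a mean TPM of at least 5, 0.53 among protein-coding genes and 0.275 without heptamer carriers, which were looked for only among genes with a mean TPM of at least 5. That of TPC-1 with FTC-133 was 0.005 with pseudocount 0.1 and -0.045 with a mean TPM of at least 5. Genes 2-fold apart with a mean TPM of at least 5 numbered 1399 in 8505C, 1418 in CAL-62, 692 in TPC-1 and 980 in FTC-133, and among protein-coding genes 1536, 1404, 718 and 1100. With FPKM as deposited they numbered 527 in TPC-1 and 766 in FTC-133. Of the named genes and list members 899 values kept their direction and 1 reversed, PER2, whose siRNA change of -0.061 was 0.051 after rescaling. The cause of these shifts was not tested.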

Other observations

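In this part the tests of siRNA seeds and of GC content and length were chosen only after the change shared by the siRNA lines was seen, while the regrouping of libraries was written before.

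The change shared by 8505C and CAL-62 may come in part from siRNA seeds rather than from NR1D1, a hypothesis. ATGAGCA was the heptamer with the lowest score of 15335 in both lines (-9.64 and -6.37, beside -1.09 in TPC-1 and -0.52 in FTC-133), and TACATTT had the highest (10.91 and 9.29), though in 8505C its carriers had a mean of 0.06 beside 0.11 for other genes before adjustment for UTR length, GC content and expression. CATGAGC and AGGATT both lie in 1 site of 19 bases in the coding part of NR1D1, positions 1940 to 1958 of its transcript, as the strands of a single siRNA duplex would require, a placing looked for only once the heptamers were chosen. Of 155 genes 2-fold lower in both lines 107 carried a candidate NR1D1-siRNA heptamer, against a median of 58 (48 to 68) in length-matched sets, which is in line with seeds as the cause of part of the falls, though the heptamers were picked on the same data; candidate control-siRNA heptamers were in 39 of 125 genes 2-fold higher in both lines, at the median of 39 (31 to 49) in matched sets, which shows no such excess for the rises. The correlation was 0.518 among 3539 genes with no core of 6 bases, so the shared change was not confined to genes with a core. Such genes may still change downstream of genes with a core, and only 1 3' UTR per gene was searched. Whether seeds were the whole cause is therefore not settled. A correlation of 0.579 after trends in GC content, length and expression were fitted, beside 0.564 before, counts against those trends.

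The 4-line comparison, oriented by NR1D1, could reflect structure other than NR1D1. Turning the lines gives 8 groupings of the same pairs, of which 4 had at least 720 genes at unadjusted p under 0.05 and 4 had at least 13 lists. The highest other grouping had 1346 genes and set treated against control libraries, and the highest for lists had 15. With 8 groupings no share can fall under 0.05.

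Several values give hypotheses about NR1D1 itself. BMAL1, ALDH5A1 and WWTR1 were each on opposite sides with siRNA and with the vector. For ALDH5A1 and WWTR1 this was fixed by the naming rule, which asked for 1 direction in all 4 lines. Such a direction was found for 10.09% of genes, beside 12.5% for independent lines with either sign equally likely, so it gives no support by itself. BMAL1 is a known target of REV-ERB alpha, so a repression still at work in these lines might be looked for first there. ALDH5A1 and WWTR1 carry heptamers that are candidates for seed matches and BMAL1 carries none, and as the siRNA sequences were not given, whether the siRNA values of the former come from seeds stays open. With the vector NR1D1 was 1.1 and 1.299 times its level with the empty vector, but as the exons in the vector were not given, this may not measure how far NR1D1 was raised. Among searched genes the correlation of the siRNA lines was 0.564, and 0.518 for those with no core of 6 bases. A second siRNA with another seed and a rescue by NR1D1 would separate these readings.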
